A study of Danio rerio with 20 samples.

How the data were processed

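Editing was measured by amplicon sequencing of genomic DNA from zebrafish melanomas. Tumours had been made by TEAZ, the electroporation of transgenes into the skin of adult fish, and cells positive for tdTomato and for the DNA dye Hoechst had been sorted before DNA was extracted, per the labels' protocols. Each target was amplified from 50 to 100 ng of DNA as a product of 200 to 280 bp with the guide site within 100 bp of an end, per the labels' protocols. The 20 samples covered 6 single guide RNAs against 3 genes, with acaa2-sg1, acaa2-sg2, tlr4ba-sg2 and tlr4bb-sg2 read in fish 1 to 4, and tlr4ba-sg1 and tlr4bb-sg1 read in fish 3 and 4.

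The values were deposited as counts of reads per allele, 1 table per guide with 1 column per fish, per the file headers. Genome build GRCz10 and R 4.0.5 were named in the submitters' processing notes. The aligner, the variant caller and any filter on reads or alleles were not given in the sources used here. Alleles carried a start position, a length and a letter, with D for a deletion and I for an insertion. Positions ran from -1 to 1 without a 0, and the boundary between them is called position 0 here. Indel starts ran from -26 to 11, and substitutions were listed from -8 to 6. Substitution-only alleles carried the prefix SNV, unmodified reads were counted as no variant, and reads without a described allele were counted as Other. Each column was tied to a sample by the guide of its table and the fish number in its header, and 0 columns belonged to no listed sample. Guide sequences, genome coordinates and the exon or intron at each site were not analysed here, so frameshift refers to the length of an indel only. In the gene order of assembly GRCz12tu, whose coordinates were not used, tlr4ba, tlr4al and tlr4bb were consecutive on 1 chromosome and acaa2 lay on another. That assembly also lists tlr4ba as a synonym of tlr4al, so which of these genes the tlr4ba guides were designed on was not settled here.

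Reads counted as Other were left out, and the remaining reads are called classified reads. The indel percent was the share of classified reads with at least 1 insertion or deletion. Among indel reads, the frameshift percent was the share whose net length change was not a multiple of 3, the insertion percent was the share with a net gain of bases, and the top allele percent was the share of the most abundant indel allele. Substitution-only reads counted as unedited. Samples needed at least 100 classified reads, which every sample had. Totals ran from 28353 to 729540 reads per sample, and the widest 95% Wilson interval of an indel percent spanned 0.684 percentage points. A count of 0 was taken to allow up to 3 reads. Reads from PCR without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only and not amplification bias. All 26 pairs of samples of a guide differed in their allele counts by far more than sampling noise (chi-square per degree of freedom 34.9 or more), so no sample was treated as a repeat of another.

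The sample was the unit of the guide comparisons, and the fish was the unit of the comparison of knockouts. Samples were compared in 6 ways: the guides of acaa2, of tlr4ba and of tlr4bb, the second guides of tlr4ba and tlr4bb, their first guides, and the acaa2 fish against the tlr4 fish after averaging over the guides of each fish number. Each of the 4 measures was compared by an exact two-sided permutation test of the difference of means, with a threshold of 0.05 on the unadjusted p and Benjamini-Hochberg values over the 24 comparisons. In the guide comparisons both groups held samples of the same fish numbers, and this test treated them as independent and ignored the pairing. The smallest p such a test can give was 0.0286 with 4 against 4 samples, 0.133 with 2 against 4 and 0.333 with 2 against 2. A count model across features was not applied, because guides cut different sites and their alleles cannot be matched. Within a knockout, the same fish number was read as the same animal, which the labels do not state outright. Over all pairs of guides read in a fish of a knockout, the mean gap in indel percent was 27.8 points, against 37.1 points over the 2304 reassignments of fish numbers, and 0.083 of these gave a summed gap as low. The fish number as a replicate block was an alternative, with a smallest p of 0.125 with 4 pairs and 0.5 with 2 pairs. Where both groups held the same fish numbers, the block leaves the mean difference unchanged.

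The alleles named were, for each guide, the 5 indel alleles with the highest mean share of classified reads and the most abundant indel allele of each sample, plus any substitution allele at 5% or more of the classified reads of a sample. Measures, comparisons, this rule and the first set of alternatives were fixed before the data were examined. That set counted Other reads as indels or as unedited, left substitution-only reads out or counted them as edited, removed alleles with 1 read or under 1% of reads, and kept only indels reaching within 10 bp of position 0. It also left out alleles with several indels and used no minimum or a minimum of 1000 classified reads. Differences were taken on the log2 odds scale with 0.5 added to each count. It counted any allele holding an insertion, took the top allele over classified reads, used the second guides alone and applied the replicate block. Last, it left out each sample in turn, or each fish in the comparison of knockouts. In guide comparisons the same fish then stayed in the other group. After seeing the data, fish 1 and 2 alone, fish 3 and 4 alone, and a minimum of 1000 indel reads were added. The first tlr4 guides were read in fish 3 and 4 only, so fish 3 and 4 alone repeats their main values. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated samples, the known share lay in the Wilson interval in at least 187 of 200 samples for each measure. Of simulated comparisons of 4 against 4 samples, 0 of 100 without a difference and 99 of 100 with a shift of 5 SD passed the threshold. No unedited tissue or control amplicon was analysed here, so the background of sequencing and alignment errors at each site was not measured.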

Results

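The series asked which insertions and deletions 6 Cas9 guides left in zebrafish melanomas. By their names, the guides were directed against acaa2, tlr4ba and tlr4bb. The gene acaa2 encodes a mitochondrial thiolase of fatty acid beta-oxidation. The genes tlr4ba and tlr4bb are among the zebrafish paralogs of the Toll-like receptor 4 gene of innate immunity. Tumours came from 4 acaa2 knockout fish and 4 tlr4 knockout fish. Depth was 114697 to 252008 reads per sample for acaa2-sg1, 282721 to 729540 for acaa2-sg2, 381962 to 453413 for tlr4ba-sg1, 28353 to 612348 for tlr4ba-sg2, 205987 to 242556 for tlr4bb-sg1 and 100378 to 322819 for tlr4bb-sg2. In the tlr4 fish, the 4 samples of fish 1 and 2 held 76301 reads on average and the 8 samples of fish 3 and 4 held 375361.

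Across the 6 guides, 26 indel alleles reached 1% of the classified reads in at least 1 fish. Of these, 23 were deletions and 3 were insertions, all 3 of 1 bp, and they changed 1 to 21 bp. Of the 26 alleles, 20 changed the length by a number of bases that is not a multiple of 3. There were 8 such alleles at the acaa2-sg1 site, 3 at acaa2-sg2, 3 at tlr4ba-sg1, 5 at tlr4ba-sg2, 0 at tlr4bb-sg1 and 7 at tlr4bb-sg2. Only 7 of the 26 alleles reached 1% in more than 1 fish. Of the 24 comparisons tested, 0 had an unadjusted exact permutation p under 0.05, and the lowest Benjamini-Hochberg value was 0.600. Those with a group of 2 samples could not pass, whatever their values. The smallest p this test can give was 0.133 for the tlr4ba and the tlr4bb guides and 0.333 for the first guides.

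**Figure D1:**
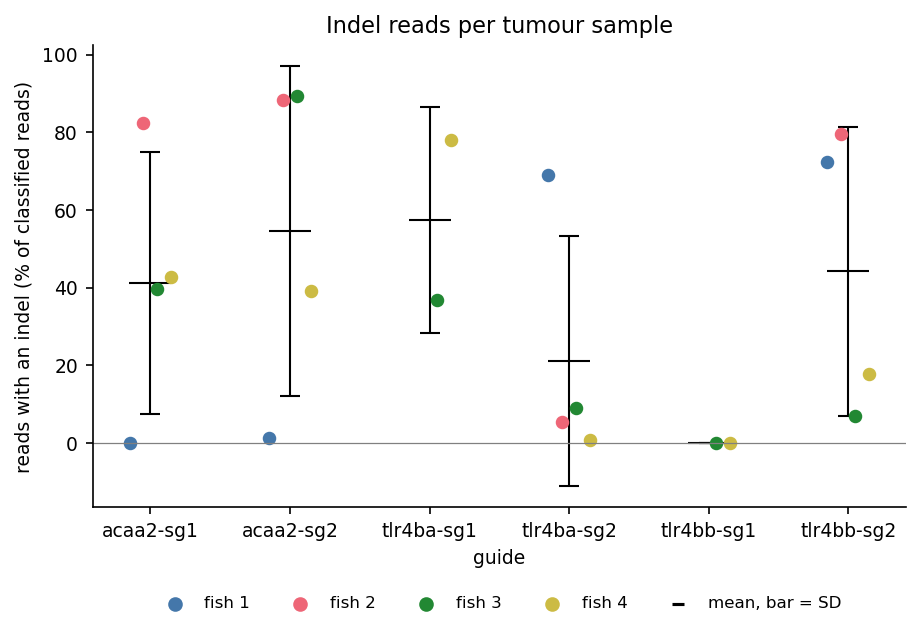
Indel reads in percent of classified reads (vertical axis) for each guide (horizontal axis), with 1 point per fish and the mean ± SD of each guide, the symmetric SD bar of tlr4ba-sg2 passing below 0. Both tlr4bb-sg1 samples lie at 0.044% and 0.045%, while samples of the other guides spread from 0.078% to 89.2%.

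The acaa2 guides asked whether either site of the gene was edited in the tumours. Both sites carried indels in most of the reads of fish 2 and in few of the reads of fish 1. At acaa2-sg1 the indel percent was 0.078% in fish 1 (161 reads; 95% Wilson interval 0.067 to 0.091), 82.4% in fish 2, 39.6% in fish 3 and 42.7% in fish 4, with a mean of 41.2% ± 33.6 (SD, n = 4). At acaa2-sg2 it was 1.36% in fish 1, 88.3% in fish 2, 89.2% in fish 3 and 39.1% in fish 4, with a mean of 54.5% ± 42.5 (SD, n = 4). The difference between the guides, -13.3 percentage points, was smaller than the spread between fish (exact permutation p = 0.514).

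A few alleles made up most of the indel reads in each edited acaa2 tumour. At acaa2-sg1, fish 2 carried a 2-bp deletion from position 1 (1:2D, 44.4%, 95% interval 44.1 to 44.7) and a 7-bp deletion from the same position (1:7D, 37.0%). The 7-bp allele had 0 reads in fish 3 and fish 4, which allows up to 0.00135% and 0.00122%. Fish 3 carried mainly a 1-bp deletion (1:1D, 32.5%, interval 32.3 to 32.7). In fish 4 a 12-bp deletion (-6:12D, 18.4%, interval 18.3 to 18.6) and a 10-bp deletion (-11:10D, 17.9%) were nearly equal, and neither had a read in another fish. The most abundant indel of fish 1 was a 1-bp deletion at position 5 (5:1D) with 87 reads, or 0.042%. This allele also had 7 reads in fish 2, 41 in fish 3 and 43 in fish 4, and it could not be set against an error background. At acaa2-sg2, a 1-bp deletion at position -2 (-2:1D) took 88.2% of the reads of fish 2 (interval 88.1 to 88.3), 38.5% of fish 4, 2.38% of fish 3 and 0.0039% of fish 1. Fish 3 carried a 14-bp deletion (-16:14D, 51.0%) and a 12-bp deletion (-15:12D, 35.4%) as its main alleles. Fish 1 held a 12-bp deletion (-6:12D, 0.900%) and an 8-bp deletion (-3:8D, 0.431%), both with 0 reads in the other fish.

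Substitution-only reads were most abundant in acaa2 fish 1. The substitution allele SNV:3G, named by its position and read base, took 14.0% of the classified reads of acaa2-sg1 fish 1 (interval 13.9 to 14.2), 2.50% of fish 2, 1.02% of fish 3 and 0.982% of fish 4. Substitution-only reads made up 15.0% of acaa2-sg1 fish 1 and 12.3% of acaa2-sg2 fish 1, and 0.203% to 6.54% of the other acaa2 samples. Among reads without an indel, substitution-only reads made up 15.0%, 15.9%, 10.8% and 11.4% in acaa2-sg1 fish 1 to 4, and 12.4%, 12.6%, 1.89% and 1.90% in acaa2-sg2 fish 1 to 4.

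Among acaa2 indel reads, 88.7% ± 21.8 (SD, n = 4) shifted the reading frame by length at acaa2-sg1 and 73.4% ± 32.6 (SD, n = 4) at acaa2-sg2, a difference of 15.3 points (exact permutation p = 0.714). The lower frameshift percents came from samples rich in 12-bp deletions, with 56.1% in acaa2-sg1 fish 4, 33.5% in acaa2-sg2 fish 1 and 60.3% in acaa2-sg2 fish 3, while the other 5 acaa2 samples lay at 99.4% or above. Insertions took 6.55% ± 9.57 (SD, n = 4) of the indel reads at acaa2-sg1 and 0.131% ± 0.161 (SD, n = 4) at acaa2-sg2, 6.41 points apart (exact permutation p = 0.057, Benjamini-Hochberg 0.600). This insertion difference was positive in all 4 fish, at 20.5, 0.208, 4.95 and 0.026 points (exact sign-flip permutation p = 0.125, the smallest that 4 pairs allow). The highest insertion percent, 20.5%, came from the 161 indel reads of acaa2-sg1 fish 1, and without the sample of under 1000 indel reads the difference was 1.76 points. The top allele held 58.3% ± 16.6 (SD, n = 4) of the indel reads at acaa2-sg1 and 80.3% ± 21.9 (SD, n = 4) at acaa2-sg2, a difference of -22.1 points (exact permutation p = 0.171).

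Fish 1 and 2 had substitution shares unlike those of fish 3 and 4, so the acaa2 differences were also taken within each pair of fish. The indel difference was -3.60 points in fish 1 and 2 and -23.0 points in fish 3 and 4. It was 0.407 points without acaa2-sg1 fish 1, with fish 1 kept at acaa2-sg2. The frameshift difference was 32.9 and -2.30 points, the insertion difference 10.3 and 2.49 points, and the top allele difference -28.9 and -15.2 points, in the same order. Without alleles under 1% of reads, the frameshift difference was -2.05 points and the insertion difference 1.58 points, and on the log2 odds scale the frameshift difference was -0.29.

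**Figure D2:**
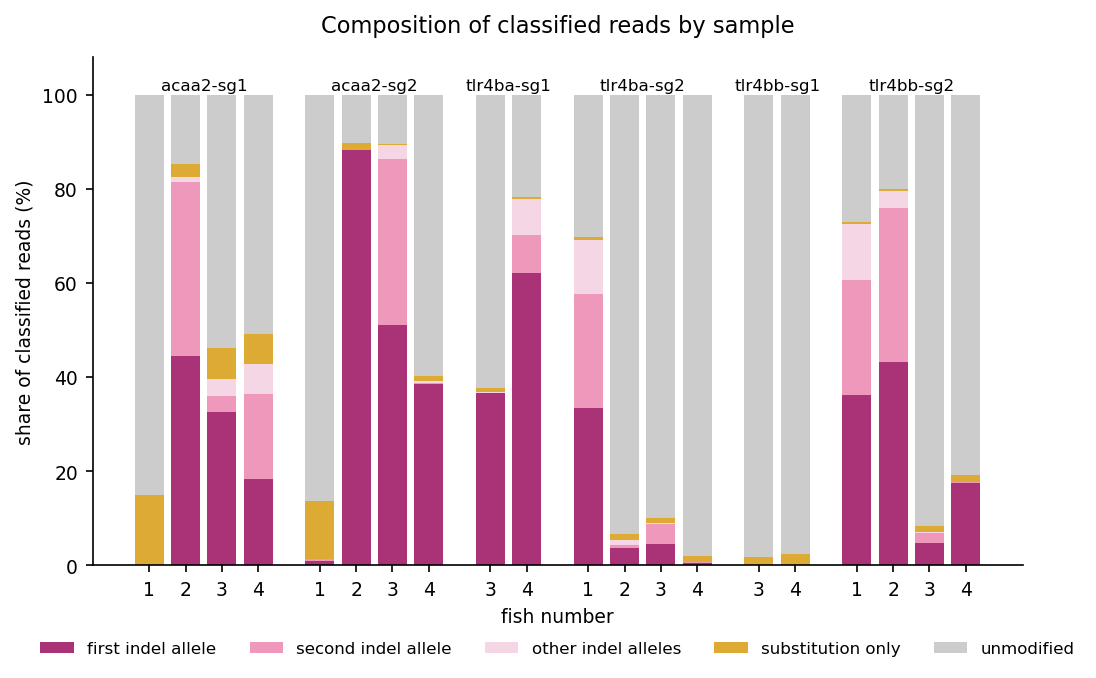
Classified reads of each sample divided into the most abundant indel allele, the second indel allele, other indel alleles, substitution-only reads and unmodified reads (vertical axis, percent), with 1 bar per fish number grouped by guide. A single allele fills most of the indel share in acaa2-sg2 fish 2 (88.2%) and tlr4ba-sg1 fish 3 (36.6%), while acaa2-sg1 fish 4 holds alleles at 18.4% and 17.9%.

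At tlr4ba, the first site carried indels in both fish read, and the second carried a high share in 1 of 4. The indel percent at tlr4ba-sg1 was 36.8% in fish 3 and 77.9% in fish 4, with a mean of 57.4% ± 29.0 (SD, n = 2). At tlr4ba-sg2 it was 69.2% in fish 1 (95% Wilson interval 68.8 to 69.5), 5.39% in fish 2, 9.01% in fish 3 and 0.736% in fish 4, with a mean of 21.1% ± 32.2 (SD, n = 4). The difference was 36.3 points (exact permutation p = 0.267), in a design whose smallest p is 0.133.

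A single 1-bp deletion at position -14 (-14:1D) led at tlr4ba-sg1, with 36.6% of the reads of fish 3 (interval 36.5 to 36.8) and 62.0% of fish 4 (interval 61.9 to 62.2). It made up 99.5% and 79.6% of their indel reads, and whether it was present before editing was not measured, since no unedited tissue was analysed here. Fish 4 also carried a 12-bp deletion (-14:12D, 8.19%), a 5-bp deletion (-17:5D, 6.34%), a 4-bp deletion (-17:4D, 0.753%) and a 3-bp deletion (-15:3D, 0.222%). In fish 3, 1 read held the 5-bp deletion and 0 reads held the other 3, which allows up to 0.000786%. Indels at this guide lay away from position 0, and only 0.149% of the indel reads of fish 3 and 10.6% of those of fish 4 reached within 10 bp of it. With only such indels counted, the mean indel percent of tlr4ba-sg1 was 4.14% and the difference from tlr4ba-sg2 was -16.9 points. At tlr4ba-sg2, fish 1 carried a 2-bp deletion (-2:2D, 33.4%, interval 33.1 to 33.8), a 1-bp insertion (-1:1I, 24.3%), a 3-bp deletion (-4:3D, 6.23%) and a 4-bp deletion (-4:4D, 4.38%). The 2-bp and 4-bp deletions returned in fish 3 at 4.30% and 4.47%. A 5-bp deletion (-5:5D) led in fish 2 at 3.66% and in fish 4 at 0.495%.

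Frameshift lengths made up 94.6% ± 7.64 (SD, n = 2) of the indel reads at tlr4ba-sg1 and 94.8% ± 5.92 (SD, n = 4) at tlr4ba-sg2 (difference -0.162 points, exact permutation p = 0.933). Insertions made up 0.225% ± 0.070 (SD, n = 2) at tlr4ba-sg1 and 15.8% ± 18.4 (SD, n = 4) at tlr4ba-sg2 (difference -15.6 points, exact permutation p = 0.800), with 35.5% in fish 1 and 27.6% in fish 4 of tlr4ba-sg2. The top allele held 89.5% ± 14.0 (SD, n = 2) and 58.3% ± 10.8 (SD, n = 4) of the indel reads (difference 31.3 points, exact permutation p = 0.133). Within fish 3 and 4, the only pair read with both guides, the tlr4ba differences were 52.5 points for indels, -5.25 for frameshifts, -13.6 for insertions and 31.1 for the top allele. With only indels within 10 bp of position 0 counted, the mean frameshift percent of tlr4ba-sg1 was 47.8%, and the differences were -46.9 points for frameshifts (exact permutation p = 0.400) and 10.2 points for the top allele, while without alleles under 1% the frameshift difference was -2.31 points. On the log2 odds scale the frameshift difference was 1.76, and it ran from -5.56 to 5.24 points with each sample left out in turn.

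**Figure D3:**
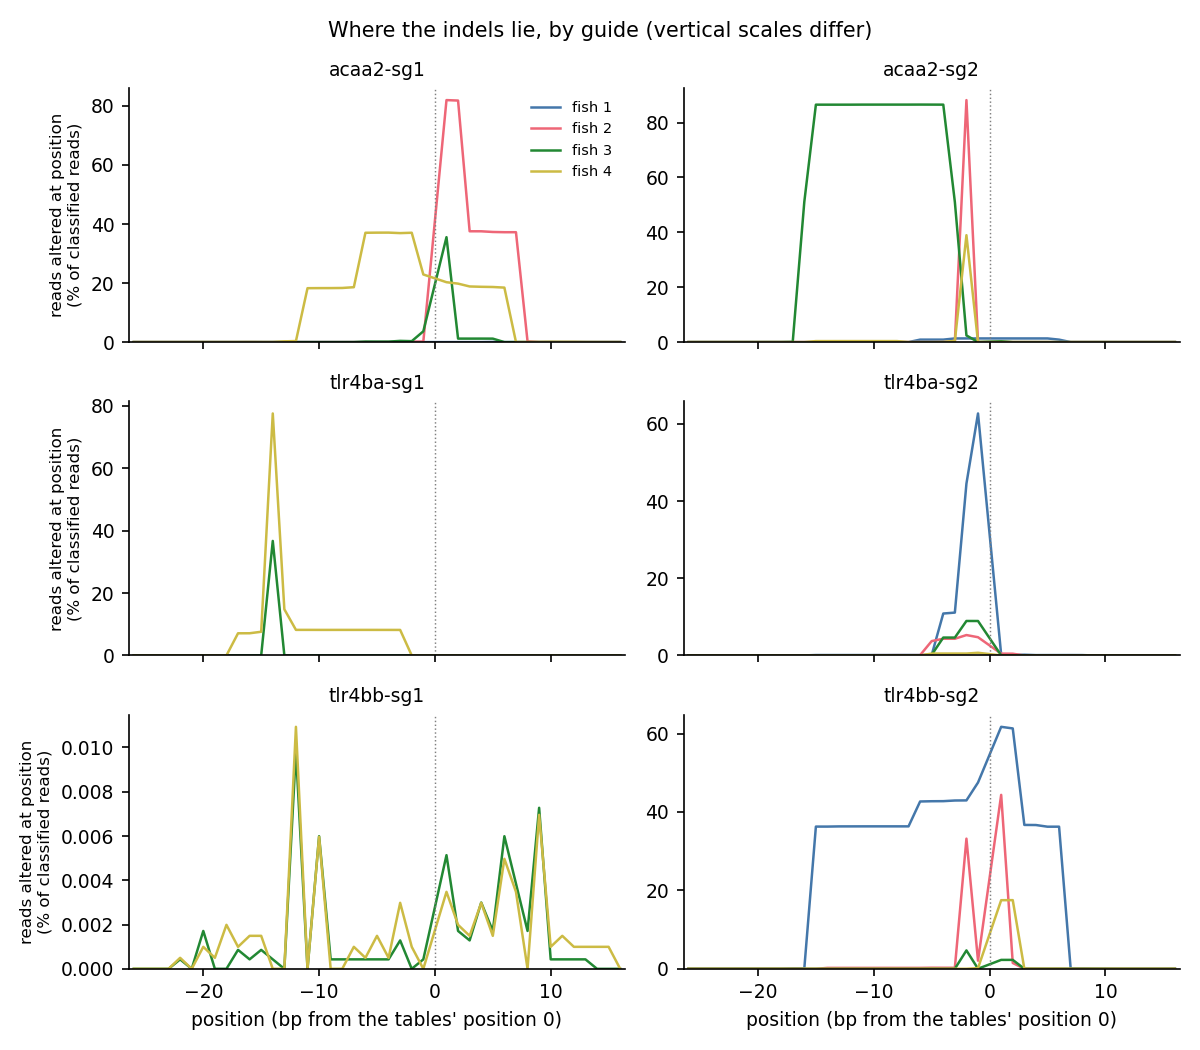
Share of classified reads with a base deleted or an insertion at each position (vertical axis, percent) against position in bp relative to position 0 (horizontal axis), with 1 panel per guide, each on its own vertical scale, and 1 line per fish. The mean over fish, which is not drawn, peaks at position 1 for acaa2-sg1 and tlr4bb-sg2, -2 for acaa2-sg2, -1 for tlr4ba-sg2 and -14 for tlr4ba-sg1. Single fish can differ, as acaa2-sg2 fish 3 has 2.43% at position -2 and 86.5% at position -8.

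At tlr4bb, the first site carried almost no indels and the second carried indels in all 4 fish. The indel percent at tlr4bb-sg1 was 0.044% in fish 3 (102 reads; 95% Wilson interval 0.036 to 0.053) and 0.045% in fish 4 (91 reads; interval 0.037 to 0.056), with a mean of 0.044% ± 0.0011 (SD, n = 2). At tlr4bb-sg2 it was 72.5% in fish 1, 79.6% in fish 2, 7.02% in fish 3 and 17.8% in fish 4, with a mean of 44.2% ± 37.1 (SD, n = 4). The difference was -44.2 points (exact permutation p = 0.133, the smallest this design allows), with both tlr4bb-sg1 samples below all 4 tlr4bb-sg2 samples. Reads without a described allele made up 3.65% and 2.31% of all reads of these tlr4bb-sg1 samples, and with such reads counted as indels the tlr4bb-sg1 mean was 3.03%.

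The indel reads at tlr4bb-sg1 spread over 24 alleles in fish 3 and 26 in fish 4. The 5 with the highest mean share were 1-bp deletions at positions -12, -10, 9, 6 and 1. The most abundant, -12:1D, had 22 reads in fish 3 and 21 in fish 4, and -10:1D, 9:1D, 6:1D and 1:1D had 7 to 14 reads per fish. Without unedited tissue, these counts could not be set against an error background. At tlr4bb-sg2, a 2-bp deletion from position 1 (1:2D) was in all 4 fish, at 24.6% of the reads of fish 1, 1.07% of fish 2, 2.27% of fish 3 and 17.5% of fish 4. Fish 1 also carried a 21-bp deletion (-15:21D, 36.2%, interval 35.9 to 36.5) and a 6-bp deletion (-6:6D, 6.34%). Fish 2 carried a 1-bp deletion (1:1D, 43.1%, interval 42.8 to 43.4) and a 1-bp insertion (-2:1I, 32.7%). A 1-bp deletion at position -2 (-2:1D, 4.67%) led in fish 3.

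Frameshift lengths made up 89.1% ± 1.62 (SD, n = 2) of the indel reads at tlr4bb-sg1 and 85.1% ± 29.6 (SD, n = 4) at tlr4bb-sg2 (difference 3.92 points, exact permutation p = 0.800). The 21-bp and 6-bp deletions of tlr4bb-sg2 fish 1 left it at 40.8%, with the other 3 fish at 99.8% or above. Insertions made up 1.47% ± 2.08 (SD, n = 2) and 10.4% ± 20.8 (SD, n = 4) of the indel reads (difference -8.93 points, exact permutation p = 0.933). The top allele held 22.3% ± 1.07 (SD, n = 2) and 67.3% ± 22.0 (SD, n = 4) (difference -45.0 points, exact permutation p = 0.133). Within fish 3 and 4, the only pair read with both guides, the tlr4bb differences were -12.3 points for indels, -10.8 for frameshifts, 1.46 for insertions and -60.2 for the top allele. The tlr4bb-sg1 values rest on 102 and 91 indel reads. Without alleles of several indels, the mean frameshift percent of tlr4bb-sg1 was 100% and the difference 14.8 points (exact permutation p = 0.133), while it was 7.66 points without alleles of 1 read and 0.687 within 10 bp of position 0. It turned negative on the log2 odds scale (-5.12) and without tlr4bb-sg2 fish 1 (-10.9 points). The insertion difference was 2.0 points with any allele holding an insertion counted, 3.70 on the log2 odds scale and 1.45 points without tlr4bb-sg2 fish 2, and the top allele difference was -25.4 points as a share of classified reads.

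The paralogs were then compared by guide. With the second guides, indels were on average 23.1 points fewer at tlr4ba than at tlr4bb (difference -23.1, exact permutation p = 0.200), with tlr4ba-sg2 lower in fish 1, 2 and 4 and higher in fish 3. The second guides differed by 9.62 points in frameshift percent (exact permutation p = 0.943), 5.41 points in insertion percent (exact permutation p = 0.743) and -9.05 points in top allele percent (exact permutation p = 0.514), all within the spread between fish. In fish 1 and 2 the differences were -38.8, 19.3, -2.97 and 6.03 points for indels, frameshifts, insertions and top allele, and in fish 3 and 4 they were -7.51, -0.061, 13.8 and -24.1 points. Without alleles under 1%, the second-guide differences were 1.48 points in insertion percent and -1.61 points in top allele percent. With the top allele taken as a share of all classified reads, the difference was -14.9 points. The frameshift difference was -1.60 on the log2 odds scale and -5.17 points without tlr4bb-sg2 fish 1, the insertion difference -1.15 points without tlr4ba-sg2 fish 1, and the top allele difference 1.37 points without tlr4bb-sg2 fish 4. With the first guides, read only in fish 3 and 4, tlr4ba exceeded tlr4bb by 57.3 points in indel percent and 67.2 points in top allele percent (each exact permutation p = 0.333, the smallest that 2 against 2 samples allow). The tlr4bb-sg1 top allele percents rest on 102 and 91 indel reads, which could not be set against an error background. Those of tlr4ba-sg1 are the shares of -14:1D, which cannot be told apart from an inherited deletion. Without tlr4ba-sg1 fish 4 the indel difference was 36.8 points. The first guides differed by 5.54 points in frameshift percent (exact permutation p = 0.667) and by -1.25 points in insertion percent (exact permutation p = 1). With only indels within 10 bp of position 0 counted, the first guides were 4.11 points apart in indel percent, -38.0 points apart in frameshift percent and -2.08 points apart in insertion percent. The first-guide frameshift difference was -5.40 points without alleles of several indels and 1.79 without alleles of 1 read, and the insertion difference was -12.2 points with any allele holding an insertion counted and 0.224 without alleles of 1 read.

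Averaged over the guides of each fish, acaa2 fish had indels in 47.9% ± 36.3 (SD, n = 4) of reads and tlr4 fish in 37.7% ± 25.2 (SD, n = 4), a difference of 10.2 points (exact permutation p = 0.686). The acaa2 fish ran from 0.721% in fish 1 to 85.4% in fish 2, and the tlr4 fish from 13.2% in fish 3 to 70.8% in fish 1. The acaa2 and tlr4 fish had frameshift percents of 81.1% ± 13.9 and 87.9% ± 14.9 (SD, n = 4 each; difference -6.84 points, exact permutation p = 0.571). Insertions made up 3.34% ± 4.75 and 11.6% ± 9.34 of their indel reads (SD, n = 4 each; difference -8.25 points, exact permutation p = 0.200). The top allele held 69.3% ± 6.96 and 59.1% ± 7.48 (SD, n = 4 each; difference 10.1 points, exact permutation p = 0.086). In fish 1 and 2 the knockouts differed by -13.6, 3.18, -14.1 and 13.4 points in indel, frameshift, insertion and top allele percent, and in fish 3 and 4 by 34.0, -16.9, -2.38 and 6.92 points. The tlr4 averages of fish 3 and 4 include both first guides and those of fish 1 and 2 do not, and with the second guides alone the differences were 21.9, -16.5, -13.0 and 17.5 points in the same order (exact permutation p of 0.086 for insertions and 0.229 for the top allele). The top allele difference was 0.982 points without alleles under 1% (exact permutation p = 0.971) and 4.82 points without samples of under 1000 indel reads (exact permutation p = 0.571). The frameshift difference was -4.38 and -16.2 points under these settings, and with only indels within 10 bp of position 0 the indel and frameshift differences were 16.9 and -0.684 points. On the log2 odds scale the frameshift difference was 0.55, and without acaa2 fish 2 the indel difference was -2.30 points.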

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

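All tests of explanations in this part were chosen after the values were seen. Of 32 groups of 4 fish examined for a sample far from the others, 7 had one. The count of 1.6 expected by chance assumes independent groups of normally distributed values. These values are bounded percentages, and the groups overlap, since the mean of tlr4 fish 1 includes tlr4bb-sg2 fish 1. The 7 therefore cannot be read as an excess over chance. The indel percent of tlr4ba-sg2 fish 1, 69.2%, lay far above the other 3 fish. The frameshift percents of acaa2-sg1 fish 4 (56.1%) and tlr4bb-sg2 fish 1 (40.8%) lay far below the other fish, as did the mean of tlr4 fish 1 over its guides (65.7%). The insertion percent of tlr4bb-sg2 fish 2 was 41.5%, far above the other fish of that guide. Substitution-only reads of acaa2-sg2 fish 1 stood apart at 12.3% of classified reads, but among reads without an indel their share was 12.4% in fish 1 and 12.6% in fish 2. Also, reads without a described allele stood apart in acaa2-sg1 fish 4 at 2.62% of all reads.

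The first and second guides differed in opposite directions at the paralogs in fish 3 and 4. In indel percent, tlr4ba-sg1 exceeded tlr4ba-sg2 by 52.5 points on average (27.8 and 77.2 in the 2 fish), while tlr4bb-sg1 minus tlr4bb-sg2 was -12.3 points (-6.97 and -17.7). In top allele percent the same differences were 31.1 points (49.8 and 12.3) at tlr4ba and -60.2 points (-45.0 and -75.5) at tlr4bb. The tlr4ba-sg1 values rest largely on -14:1D, which held 99.5% and 79.6% of indel reads and cannot be told apart from an inherited deletion. In tlr4ba-sg1 fish 3, other indel alleles held 771 of 381469 classified reads, while tlr4ba-sg2 fish 3 had 42911 indel reads of 476445. The tlr4bb-sg1 top allele percents rest on 102 and 91 indel reads. The difference between the paralogs in these contrasts was not tested.

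Reads without a described allele, which the comparisons left out except in the alternatives that count them as indels or as unedited, were above the limit of a count of 0 in each guide, with their highest count at 2.62% of the reads of acaa2-sg1 fish 4, 0.310% of acaa2-sg2 fish 2, 0.223% of tlr4ba-sg1 fish 4, 1.21% of tlr4ba-sg2 fish 1, 3.65% of tlr4bb-sg1 fish 3 and 0.454% of tlr4bb-sg2 fish 3. What these reads hold was not analysed here.

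Among reads without an indel, substitution shares were closer within fish 1 and 2 and within fish 3 and 4 than between these pairs, with the nearest fish being the partner in 16 of 16 samples of the 4 guides read in 4 fish. SNV:3G took 14.0% and 14.3% of such reads in acaa2-sg1 fish 1 and 2, and 1.69% and 1.71% in fish 3 and 4, while some rare alleles at the tlr4 sites differed within a pair, such as SNV:1G at 0.342% and 0.026% in tlr4ba-sg2 fish 1 and 2. Carry-over between partners as the source of all reads without an indel is argued against in 15 of 15 testable directions (of 16). In each, an indel allele of the source was at under 0.5 of the reads this would bring. Carry-over of only a part of these reads was not tested. The direction that could not be tested was acaa2-sg1 from fish 1 to fish 2, the pair highest in SNV:3G. A heterozygous variant, also one shared by related fish, is argued against by a highest share of 14.3%. Handling of fish 1 and 2 apart from fish 3 and 4 cannot be told apart from any other property that partners share, such as unedited DNA from a common source or further copies of the site amplified alongside it, since each predicts the same pairing.

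Several indel alleles recurred between fish of a guide, such as 1:2D in all 4 fish at tlr4bb-sg2. Reads carried over between fish as the whole source of these alleles are argued against in 25 of 28 directed pairs, where another allele or the unmodified reads of the source were at under 0.5 of the expected reads, and stay open in 3 (acaa2-sg2 from fish 2 to fish 3 and to fish 4, and tlr4bb-sg2 from fish 4 to fish 2). The 7 alleles at 1% or more in over 1 fish changed 1.71 bp on average and the 19 at 1% or more in a single fish 6.32 bp (exact one-sided permutation p = 0.0128). Small repair products favoured at the cuts are a hypothesis for this. The test pooled the alleles of all guides as independent, though alleles share fish and guides and tlr4ba-sg1 was read in 2 fish only. The 7 include -14:1D of tlr4ba-sg1, which cannot be told apart from an inherited deletion. Short alleles also have fewer possible forms and may coincide by chance, which this test does not separate, and no biological cause of the recurrence was tested.

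At tlr4ba-sg1 the indels lay around position -14 in both fish. Whether the numbering of this table starts away from the cut of this guide stays open, since among indel alleles other than -14:1D that position was covered by 97.8% of the reads in fish 4 and by 36.3% of the 771 reads in fish 3. An inherited 1-bp deletion as the whole of the indel reads of fish 4 is argued against, since other alleles covering the same position made up 19.9% of them. The 1-bp allele itself, at 36.6% of the classified reads of fish 3 and 62.0% of fish 4, cannot be told apart from an inherited deletion, because no unedited tissue of these fish was analysed.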

How the results depend on the processing

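The alternatives with fish 1 and 2 alone, fish 3 and 4 alone and at least 1000 indel reads were chosen after seeing the data. Over 430 alternative values of the comparisons, 397 kept the direction, some by construction, and 33 reversed. With 1 sample in a group, 32 had no test, and none of the other 398 passed the threshold (smallest exact permutation p 0.057). The cause was not tested. Groups of 2 samples, 3 against 3 and 3 against 4 cannot pass the threshold, so no value with a sample or fish left out could. The minimums of classified reads could move no comparison, since every sample passed them. The minimum of 1000 indel reads did move values, such as the acaa2 insertion difference from 6.41 to 1.76 points. Depth limits mainly the 161, 102 and 91 indel reads of acaa2-sg1 fish 1 and of the tlr4bb-sg1 fish.

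With only indels within 10 bp of position 0, the tlr4ba guide difference in indel percent was -16.9 and the first-guide difference in frameshift percent -38.0, with a tlr4ba-sg1 mean indel percent of 4.14%. On the log2 odds scale, the frameshift difference was -0.29 for the acaa2 guides, 1.76 for tlr4ba, -5.12 for tlr4bb, -1.60 for the second guides and 0.55 for acaa2 against tlr4 fish, and the insertion difference for tlr4bb was 3.70. Without alleles under 1%, the acaa2 frameshift difference was -2.05. Without alleles of several indels, the first-guide frameshift difference was -5.40. Counting any allele with an insertion, the tlr4bb insertion difference was 2.0, and without alleles of 1 read the first-guide insertion difference was 0.224.

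In fish 1 and 2 alone, acaa2 against tlr4 fish gave -13.6 for indels and 3.18 for frameshifts, and the second guides gave -2.97 for insertions and 6.03 for the top allele. In fish 3 and 4 alone, the frameshift difference was -2.30 for the acaa2 guides, -10.8 for tlr4bb and -0.061 for the second guides, and the insertion difference for tlr4bb was 1.46. With the fish number as a replicate block, the paired tlr4bb differences were -10.8 for frameshifts and 1.46 for insertions. The block could turn only tlr4ba and tlr4bb differences, and it turned no other. Its smallest possible p is 0.125 with 4 pairs and 0.5 with 2, so it could change no call.

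The mean indel percent of tlr4bb-sg1, 0.044%, became 3.03% with Other reads as indels, 0.043% with them as unedited, 2.01% with substitutions as edited, 0.039% without alleles of 1 read, 0% without alleles under 1%, 0.030% within 10 bp of position 0 and 0.040% without alleles of several indels.

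Leaving out each fish in turn, the indel difference ran from -31.0 to 0.407 for the acaa2 guides (0.407 without acaa2-sg1 fish 1) and from -2.30 (without acaa2 fish 2) to 25.9 for acaa2 against tlr4 fish. Frameshift differences ran from -5.56 to 5.24 for tlr4ba (positive without tlr4ba-sg1 fish 4, tlr4ba-sg2 fish 3 or tlr4ba-sg2 fish 4), -10.9 to 8.87 for tlr4bb and -5.17 to 14.6 for the second guides, the last 2 negative without tlr4bb-sg2 fish 1. Insertion differences ran from -12.4 to 1.45 for tlr4bb (positive without tlr4bb-sg2 fish 2), -1.15 (without tlr4ba-sg2 fish 1) to 15.8 for the second guides and -2.72 to 0.225 (without tlr4bb-sg1 fish 3) for the first guides. The top allele difference of the second guides ran from -14.8 to 1.37 (positive without tlr4bb-sg2 fish 4). Without a change of sign, the acaa2 frameshift difference ran from 2.0 (without acaa2-sg2 fish 1) to 26.2, the tlr4ba indel difference from 15.8 to 56.8 (without tlr4ba-sg1 fish 4 or fish 3), the second-guide indel difference from -39.2 (without tlr4ba-sg2 fish 1) to -11.3 (without tlr4bb-sg2 fish 2), the first-guide indel difference from 36.8 (without tlr4ba-sg1 fish 4) to 77.9, the first-guide frameshift difference from 0.137 to 10.9 and the acaa2 against tlr4 frameshift difference from -14.3 to -1.96. Insertion differences reached 1.76 for acaa2 (without acaa2-sg1 fish 1), -9.02 for tlr4ba and -5.17 for acaa2 against tlr4 fish. Fish 1 and 2 alone gave no value for the first tlr4 guides, and the shares among indel reads of tlr4bb-sg1 gave none without alleles under 1% or with at least 1000 indel reads.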

Other observations

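Both tests in this part were chosen after the values were seen. As a share of all classified reads, frameshift indels reached 88.3% in acaa2-sg2 fish 2, 82.4% in acaa2-sg1 fish 2, 79.6% in tlr4bb-sg2 fish 2, 69.5% in tlr4ba-sg1 fish 4 and 62.6% in tlr4ba-sg2 fish 1. In-frame indels took more reads than frameshift indels in tlr4bb-sg2 fish 1, at 42.9% against 29.5%, and in acaa2-sg2 fish 1, at 0.908% against 0.457%. At both acaa2 sites of fish 1, indel reads were a small part of the total, while both acaa2 sites of fish 2 were above 80% indel reads.

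Most edited samples held few alleles. The effective number of indel alleles, the inverse of the summed squared shares, was 1.0 to 2.95 in the 18 samples outside tlr4bb-sg1, against 8.83 and 9.97 in the tlr4bb-sg1 samples. A pair of alleles at similar shares led in several samples, with the second allele at 0.972 of the first in acaa2-sg1 fish 4, 0.962 in tlr4ba-sg2 fish 3, 0.832 in acaa2-sg1 fish 2, 0.759 in tlr4bb-sg2 fish 2 and 0.728 in tlr4ba-sg2 fish 1. In acaa2-sg2 fish 2 and tlr4ba-sg1 fish 3, a single allele held 99.8% and 99.5% of the indel reads. The substitution SNV:-2A, chosen after its values were seen, took 4.96% and 4.77% of the reads without an indel in acaa2-sg2 fish 1 and 2, and 0.022% and 0.037% in fish 3 and 4.

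A hypothesis was that editing at the sites of the same fish number goes together, as it may if the same tumour cells received several guides. Over the 18 within-fish gaps between the 6 guides, the mean gap in indel percent was 27.8 points, against 37.1 points over 2304 reassignments of fish numbers, and 0.083 of the reassignments gave a summed gap as low (exact one-sided permutation test). Without the first tlr4 guides, the mean gap was 19.6 points against 38.5 points over 576 reassignments, again with a share of 0.083. With them, the gap between the tlr4ba guides was 27.8 points in fish 3 and 77.2 points in fish 4. Both shares missed the threshold of 0.05, so the hypothesis stays open.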
